A study of Mus musculus with 4 samples.

How the data were processed

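The series holds 4 Affymetrix mouse whole-transcript arrays, 1 each for wild-type, MDR2-null, GHR-null and double-null livers. The mice were 8 weeks old, and per the labels and the series design each array was hybridised with RNA pooled from 3 livers of 1 genotype. The deposited table gives 1 intensity per probe set and array. Per the submitters' processing notes the values came from RMA (robust multi-array averaging, which corrects background, quantile normalizes and summarises probes) in Affymetrix Expression Console 1.1. RMA values usually come as log2. The deposited intensity values were whole numbers from 6 to 22355, that is, on a linear scale, so log2 was taken first, as the rules fixed before the data were examined foresaw. Rounding to whole numbers makes log2 differences between low intensities coarse. The authors' normalization was kept. No scanner files and no detection calls were used here, so the level above background is known only through the intensity itself.

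The table had 35556 rows. GEO's platform annotation gave 21789 of them exactly 1 gene symbol, 1621 several and 12146 none. Of the rows with 1 symbol, 21698 were matched by gene identifier to the RefSeq gene table of the assembly GRCm38.p6, and no symbol needed an update. Rows with several or no symbols were left out of the comparisons. A gene with several rows (999 of 19938 genes) took the row with the highest mean over the 4 arrays. No genome build is named for the probe sets in the sources used here, so no coordinates are given. Values correlated between arrays at a Pearson r of 0.970 to 0.988 (log2, rows with 1 symbol).

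Pairwise log2 differences were taken between single arrays, for 5 comparisons: MDR2-null against wild type, GHR-null against wild type, double-null against MDR2-null, double-null against wild type and double-null against GHR-null. A gene entered a 2-fold count only where the higher of the arrays compared was at or above the median of all rows with 1 symbol, an intensity of 100. With 1 array per genotype these are descriptions with no replicate check. Non-additivity was the difference of the differences with GHR loss with and without MDR2. Over 10764 genes its robust SD was 0.33 (log2), which gives 0.23 for a single pairwise difference. This is the spread of a typical gene and holds real non-additivity too. It is no upper limit for a given gene, since single genes can be noisier.

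The only test was limma (lmFit and eBayes on log2 values) with GHR and MDR2 status as additive factors over all 4 arrays, 1 residual degree of freedom per gene plus 4.34 prior degrees, and Benjamini-Hochberg adjustment at 0.05 over genes whose highest array passed the level filter. It assumes that an effect is the same in both backgrounds, and a gene that is not additive inflates its own residual. Tested on simulated data for the average effect of GHR loss over 10764 genes, with 200 genes changed, it recovered 56% of 2-fold and 96% of 4-fold changes, with 8 false calls.

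In total 38 gene lists were fixed before the data were examined, covering growth hormone action, sex-biased liver genes, bile acid handling, liver cell types, matrix, inflammation, stress, metabolism, other tissues, sex-linked genes and the neighbours of the targeted genes. For each list the median log2 difference of the measured members, the members at least 1.5-fold higher or lower, and the percentile of the median among 10000 random lists of the same size, matched on mean expression in 10 bins, were computed. Percentiles describe these pools and are not p-values. On 100 random lists of 20 genes from the MDR2-null against wild-type difference (19938 genes), 6% fell outside the 2.5th to 97.5th percentile, and all 100 lists shifted by 1 log2 unit lay above it. Sex-biased, cell type and pathway lists overlap in a few members.

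Genes are named by a rule fixed in advance: the targeted genes, the 8 highest and 8 lowest in each pairwise comparison and the 6 highest and 6 lowest for non-additivity among genes passing the level filter (predicted loci left out), up to 4 members with the largest difference in each list, the 5 smallest limma p-values in each direction, and a fixed panel of liver genes. Genes outside it were chosen after their values were seen and are marked so. Some fixed list and panel members had no row with 1 symbol and were not analysed here.

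Alternatives fixed in advance were no level filter, a filter at the 75th percentile (intensity 329), a 1.5-fold threshold, cyclic loess between arrays, centring each array on the median of genes passing the filter or on hepatocyte markers, the mean of all rows of a gene, list members passing the filter, and limma with trend and robust settings. Median centring moved the median of all genes by -0.12 (log2) in the GHR-null against wild-type comparison, and hepatocyte centring moved it by 0.13 in the double-null against GHR-null comparison. All other shifts were under 0.1. Leaving out the sex-biased and sex-linked lists was added after the Xist signal of the GHR-null pool was seen. A limma fit without that pool has no residual degree of freedom and could not be made. Analyses were run in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.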

Results

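Messenger RNA levels were measured in the livers of 8-week-old mice on 4 whole-transcript microarrays. The genotypes were wild type, loss of MDR2, loss of the growth hormone receptor (GHR), and loss of both. MDR2 is the protein of Abcb4, which moves phosphatidylcholine into bile; mice without it develop cholestasis, bile duct injury and liver fibrosis. GHR carries the growth hormone signal into hepatocytes, and its loss makes the liver growth hormone resistant. Each genotype was 1 array, hybridised with RNA pooled from 3 livers of mice labelled male. The series title names the question of whether growth hormone resistance worsens the fibrosis of cholestasis. There was no replicate array of any genotype, so the pairwise differences below describe these 4 pools, without a p-value. Median intensity over the 21789 rows with 1 gene symbol was 94 in the wild-type pool, 102 in the MDR2-null pool, 97 in the GHR-null pool and 105 in the double-null pool, and the number of arrays limits the precision. An intensity under 100 was not shown to be above background, so a fold against such a value is not exact.

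The targeted genes were examined first. Ghr intensity was 4944 in the wild-type pool and 4485 in the MDR2-null pool, and lower in the pools without the receptor, at 1395 in the GHR-null and 935 in the double-null pool. Abcb4 was 1120 in the wild-type and 1346 in the GHR-null pool, against 663 in the MDR2-null and 689 in the double-null pool. The Abcb4 difference was partial, and which part of either gene its probes cover is not given in the sources used here, so these values check the labels only where the probes lie in the deleted part. Xist, the RNA that silences 1 X chromosome in female cells, was 16, 18 and 17 in the wild-type, MDR2-null and double-null pools and 1400 in the GHR-null pool, although all pools are labelled male. The Y-linked genes Eif2s3y, Kdm5d and Uty were present in every pool. In the GHR-null pool they stood at 680, 259 and 308, against 899, 268 and 361 in the wild-type pool.

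**Figure D1:**
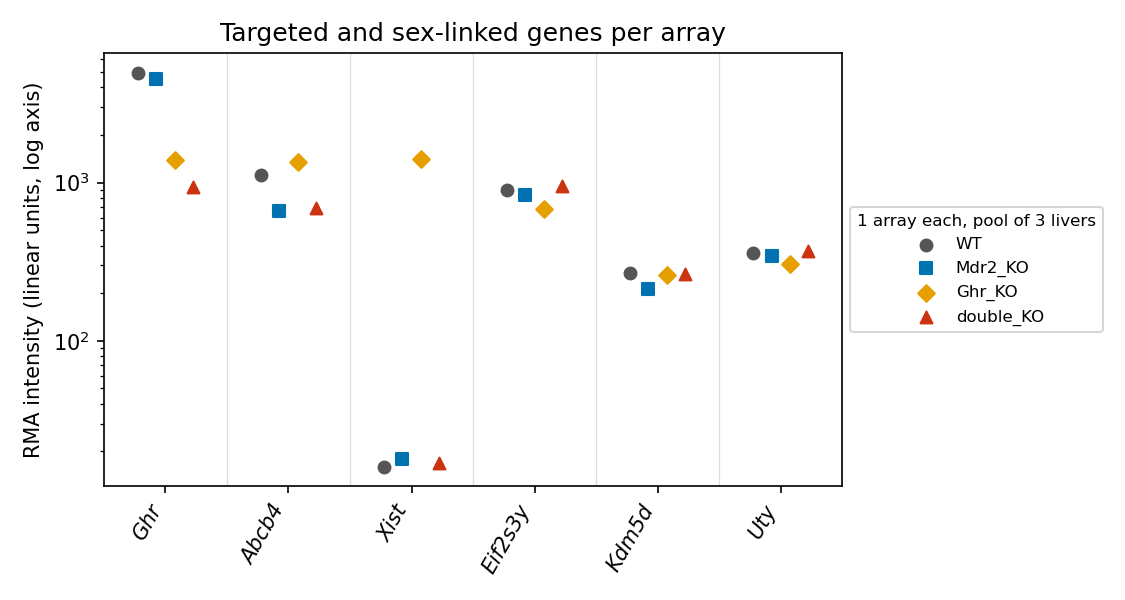
Intensity of the targeted genes Ghr and Abcb4, of Xist and of 3 Y-linked genes, on a log axis, with 1 point per array (a pool of 3 livers per genotype). Xist stands at 1400 in the GHR-null pool and between 16 and 18 in the others.

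Loss of GHR with MDR2 intact (GHR-null against wild-type pool) went with lower levels of several growth hormone targets and of male-biased liver genes, and with higher levels of female-biased ones. Igf1, the main circulating mediator of growth hormone action, was 3951 in the wild-type and 1546 in the GHR-null pool, 2.56-fold lower. Igfals, which stabilises IGF1 in blood, was 3.01-fold lower, the epidermal growth factor receptor gene Egfr was 7.73-fold lower, the transcription factor Onecut1 was 4.64-fold lower, and the signalling inhibitors Socs2 and Cish were 3.22-fold and 2.29-fold lower. Igfbp1, an IGF-binding protein raised in fasting, was 3.92-fold higher. Of 16 measured genes of the GH and IGF axis, 6 were at least 1.5-fold lower and 3 at least 1.5-fold higher, and the list median was -0.01 on the log2 scale (percentile 4.56 of the random lists).

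Male-biased liver genes were lower in 23 of 25 measured members by at least 1.5-fold, with a median of -1.61 that lay below all 10000 random lists matched on expression. Hsd3b5, a steroid-metabolising enzyme, was 3877 in the wild-type and 21 in the GHR-null pool, the fatty acid elongase Elovl3 was 2806 and 28, and the fatty acid hydroxylase Cyp4a12a was 7891 and 140. Female-biased genes were at least 1.5-fold higher in 17 of 22 members and lower in 1, with a median of 2.77 above all 10000 random lists. Cyp2b13 was 15 in the wild-type and 2545 in the GHR-null pool, Cyp2b9 was 71 and 5952, Hao2 was 19 and 1507, and the estrogen sulfotransferase Sult1e1 was 20 and 1114. These values come from the pool that also carried Xist at 1400.

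Genes of PPAR alpha and fatty acid oxidation were also higher in the GHR-null pool, 10 of 22 by at least 1.5-fold and none lower by that much, with a median of 0.47 above all 10000 random lists. Cyp4a14 was 31.0-fold, Cyp4a31 5.20-fold and Cyp4a10 4.12-fold higher. This too is the pool with Xist at 1400; between the double-null and MDR2-null pools, with Xist at 17 and 18, the same list had a median of 0.07 (percentile 88.4), which turned below 0 with median centring, and 4 of 22 members were higher. Against the wild-type pool, 6 of 16 members of the list of lipid uptake and droplets were higher in the GHR-null pool and 2 lower. Its highest were Vldlr, also on the female-biased list, at 7.83-fold and the fatty acid transporter Cd36 at 5.89-fold. The acute phase genes Saa1 and Saa2 were 5.27-fold and 4.04-fold lower, while Hamp2 was 4.30-fold higher. Over that list 4 of 26 members were higher and 4 lower. Bile acid genes split: the oxysterol hydroxylase Cyp7b1 and the uptake carrier Slco1a1 were 6.51-fold and 10.9-fold lower, while Cyp39a1, the carrier Slco1a4 and the efflux pump Abcc4 were 5.11-fold, 3.71-fold and 2.97-fold higher. Of these, Cyp7b1 and Slco1a1 are also on the male-biased list and Cyp39a1 on the female-biased list. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 2703 in the wild-type and 2621 in the GHR-null pool. Of 10 genes of bile acid sensing, 2 were higher, with a median of 0.21 (percentile 96.4). Genes of the stress response of the endoplasmic reticulum had a median of -0.20, with Asns, the asparagine synthetase, 3.36-fold lower.

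The lists of bile duct, matrix and TGF beta genes had medians of at most 0.10 in the GHR-null pool, while stellate cell, macrophage and endothelial markers had higher ones. Krt23, a keratin of bile duct cells, was 38 in the wild-type and 222 in the GHR-null pool, and Prom1, also on the female-biased list, was 2.82-fold higher. With these, 2 of 19 cholangiocyte markers were at least 1.5-fold higher and 2 lower. Medians were 0.01 for cholangiocyte markers, 0.08 for collagens and matrix, 0.07 for matrix remodelling and 0.10 for TGF beta signalling, each of which turned below 0 when arrays were centred on the median of genes passing the level filter, the cholangiocyte median also with cyclic loess and hepatocyte centring. The macrophage list had a median of 0.43, above all 10000 random lists, the stellate cell list 0.31 (percentile 99.99) and the endothelial list 0.33 (percentile 99.98). In these, 2 of 24, 2 of 20 and 1 of 19 members were at least 1.5-fold higher and none lower. In all, 107 genes were at least 2-fold higher and 99 at least 2-fold lower among 10052 compared. With median centring the counts were 85 and 121, so the share of higher calls was 41.3% in place of 51.9%.

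Loss of MDR2 with GHR intact (MDR2-null against wild-type pool) went with higher levels of bile duct, macrophage, chemokine, matrix and cell cycle genes. Lcn2, a lipocalin of the acute phase and of injured epithelium, was 652 in the wild-type and 6302 in the MDR2-null pool. The highest ratio was that of D17H6S56E-5, at 45 and 1016. Cholangiocyte markers were at least 1.5-fold higher in 14 of 19 members, with a median of 0.78. Among them the keratin Krt23 was 38 in the wild-type and 171 in the MDR2-null pool, and the epithelial adhesion molecule Epcam was 2.35-fold and Wfdc2 2.28-fold higher. Kupffer cell and macrophage markers were higher in 17 of 24 members, with a median of 0.93, led by the chemokine receptor Ccr2 at 4.07-fold and the lysozyme Lyz2 at 3.40-fold. Chemokines, cytokines and adhesion molecules were higher in 15 of 26 members, with a median of 0.75. Ccl2, which attracts monocytes, was 4.60-fold, Cxcl16 2.97-fold and Vcam1 2.71-fold higher. No member of these lists was 1.5-fold lower, and each median lay above all 10000 random lists.

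Collagens and matrix genes were at least 1.5-fold higher in 10 of 29 members, with a median of 0.48. The collagen genes Col1a1, Col1a2 and Col3a1 were 1.98-fold, 2.21-fold and 1.96-fold higher. Matrix remodelling genes were higher in 9 of 19, led by Timp1, an inhibitor of matrix proteases, at 3.23-fold and the macrophage elastase Mmp12 at 2.61-fold. TGF beta and profibrotic genes were higher in 9 of 18, with Tgfb2 at 2.52-fold and the matricellular gene Ccn2 at 2.06-fold. Stellate cell and myofibroblast markers were higher in 5 of 20, among them Acta2, the smooth muscle actin, at 2.16-fold. Cell cycle genes were higher in 13 of 29, with cyclin D1 (Ccnd1) at 5.20-fold and Ccna2 at 2.47-fold, from 36 in the wild-type to 89 in the MDR2-null pool. In the p53 and apoptosis list 5 of 20 members were higher, with Casp12 at 3.15-fold, and in the list of oxidative stress genes 5 of 27, with the NADPH oxidase subunit Cybb at 6.40-fold. No member of these lists was 1.5-fold lower. Endothelial and hepatocyte markers had medians of 0.01 and -0.04, the first turning below 0 with hepatocyte centring.

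Lower in the MDR2-null pool were genes of fatty acid synthesis and targets of the drug-sensing receptors CAR and PXR. Fatty acid synthesis genes were at least 1.5-fold lower in 7 of 18 members and higher in 1, with a median of -0.45. The carboxylase Acacb was 2.23-fold and the acyltransferase Gpam 1.68-fold lower, and the higher member was the desaturase Scd2 at 1.60-fold. CAR and PXR targets were lower in 6 of 17 and higher in 1, with a median of -0.37, and Ces2a was 2.99-fold lower. The PPAR alpha list had a median of -0.24, 3 of 22 members lower and 1 higher, with Cyp4a31 at 416 in the wild-type and 104 in the MDR2-null pool, and Cyp4a14 and Cyp4a10 3.83-fold and 3.71-fold lower. Cholesterol synthesis genes had a median of -0.04, which turned above 0 with cyclic loess, and 2 of 18 were lower. In the list of lipid uptake and droplets 2 of 16 members were higher and none lower, Cd36 at 2.40-fold and Lpl at 1.96-fold. Bile acid synthesis genes had a median of -0.28 with no member 1.5-fold apart, and canalicular and uptake transporters one of -0.33. The basolateral efflux gene Slc51b was 2.57-fold higher. Of the male-biased genes, 8 of 25 were lower, among them Hsd3b5 at 10.6-fold. Igf1 was 3951 in the wild-type and 3766 in the MDR2-null pool. In all, 241 genes were at least 2-fold higher and 78 at least 2-fold lower among 10258 compared.

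Loss of GHR in the cholestasis model (double-null against MDR2-null pool) is the comparison the series title names. Cholangiocyte markers, fetal liver and tumour markers, matrix remodelling and TGF beta genes were higher than with loss of MDR2 alone, while the collagens differed little. Cholangiocyte markers were at least 1.5-fold higher in 14 of 19 members and lower in none, with a median of 0.99. Tspan8 was 4.26-fold, the chloride channel Cftr 3.92-fold and Epcam 2.91-fold higher, and the keratins Krt7 and Krt19 were 2.18-fold and 1.75-fold higher. Fetal liver and liver tumour markers were higher in 13 of 24 members and lower in 1, with a median of 0.93. In the MDR2-null against the wild-type pool that list had a median of 0.29, with 7 of 24 members higher and 1 lower. Alpha-fetoprotein (Afp) was 58 in the wild-type, 55 in the MDR2-null and 259 in the double-null pool, the RNA-binding protein Igf2bp3 was 46, 38 and 267, and Bex1 was 18, 20 and 229 in these pools. The double-null against MDR2-null medians of the cholangiocyte and fetal lists lay above all 10000 random lists.

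Matrix remodelling genes were higher in 12 of 19 members, with a median of 0.69. Mmp7, a protease of bile duct epithelium, was 4.44-fold, Mmp12 2.81-fold and Timp1 1.78-fold higher. TGF beta and profibrotic genes were higher in 10 of 18, with a median of 0.64, and Ccn2 was 532 in the MDR2-null and 2197 in the double-null pool. Collagens and matrix genes had a median of 0.11 at percentile 89.4, with 4 of 29 members at least 1.5-fold higher. Those with the largest differences were the proteoglycans Vcan at 3.03-fold and Lum at 2.23-fold. Col1a1 was 373 in the MDR2-null and 423 in the double-null pool, Col3a1 was 353 and 311, and Acta2 was 324 and 223. The stellate cell list had a median of 0.11, with 4 of 20 members higher and 2 lower. Macrophage markers were higher in 10 of 24, with a median of 0.50, led by Cx3cr1 at 3.13-fold. Chemokine, cytokine and adhesion genes had a median of 0.41 at percentile 100. Of these, 10 of 26 were higher, among them Ccl2 at 4.11-fold and Ccl20 at 2.71-fold. Another 2 were lower, among them the interferon-induced Cxcl9 at 5.88-fold. Cell cycle genes had a median of -0.02, which turned above 0 with cyclic loess and hepatocyte centring, and no member was 1.5-fold apart. Oxidative stress genes had a median of -0.03 (percentile 42.0), which turned above 0 with hepatocyte centring, and were higher in 6 of 27 and lower in 1, with the heme oxygenase Hmox1 at 1.75-fold and Gpx3 at 2.51-fold, and p53 and apoptosis genes were higher in 4 of 20.

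Several growth hormone targets were lower in the double-null than in the MDR2-null pool. Igf1 was 3766 and 374, 10.1-fold lower, and Igfals was 11.1-fold, Egfr 4.85-fold and Cish 3.37-fold lower. Socs2 was 535 in the MDR2-null and 605 in the double-null pool, and Igfbp1 was 9.30-fold higher. Of 16 genes of the GH and IGF axis, 6 were at least 1.5-fold lower and 2 higher, with a median of -0.32. The male-biased list was at least 1.5-fold lower in 19 of 25 members, with a median of -2.34. The female-biased list was higher in 12 of 22 and lower in 1, with a median of 0.77, and Sult1e1 was 36 and 1845, Cyp2b9 was 51 and 1162, and Abcd2 was 10.1-fold higher. Xist was 18 and 17 in these pools. Thrsp, a regulator of lipogenesis, was 2796 in the MDR2-null and 113 in the double-null pool. With it the fatty acid synthesis list was lower in 8 of 18 members and higher in 1, with a median of -0.40. Cholesterol synthesis genes had a median of -0.34 with 6 of 18 lower, among them Mvd at 1.90-fold and Fdps at 1.74-fold. The periportal gene Cyp2f2, also on the male-biased list, was 15.2-fold lower. Acute phase genes went both ways, 7 of 26 lower and 4 higher, with Saa1 11.7-fold lower and Hamp2 5.51-fold higher. So did bile acid synthesis genes, 4 of 15 lower and 2 higher, with Cyp8b1, a bile acid hydroxylase, 3.89-fold lower and Cyp39a1, also on the female-biased list, 6.85-fold higher. Canalicular and uptake transporters had 2 of 11 members lower and 2 higher, with a median of 0.06 that turned below 0 with cyclic loess and median centring. The uptake carrier Slc10a1 was 1.93-fold lower, Slco1a4 was 3.08-fold higher and the sterol transporter Abcg5 2.02-fold higher. Hepatocyte markers had a median of -0.04, which turned above 0 with cyclic loess, and endothelial markers one of -0.17. In all, 243 genes were at least 2-fold higher and 164 at least 2-fold lower among 10524 compared. With median centring the counts were 184 and 190, so the share of higher calls was 49.2% in place of 59.7%.

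**Figure D2:**
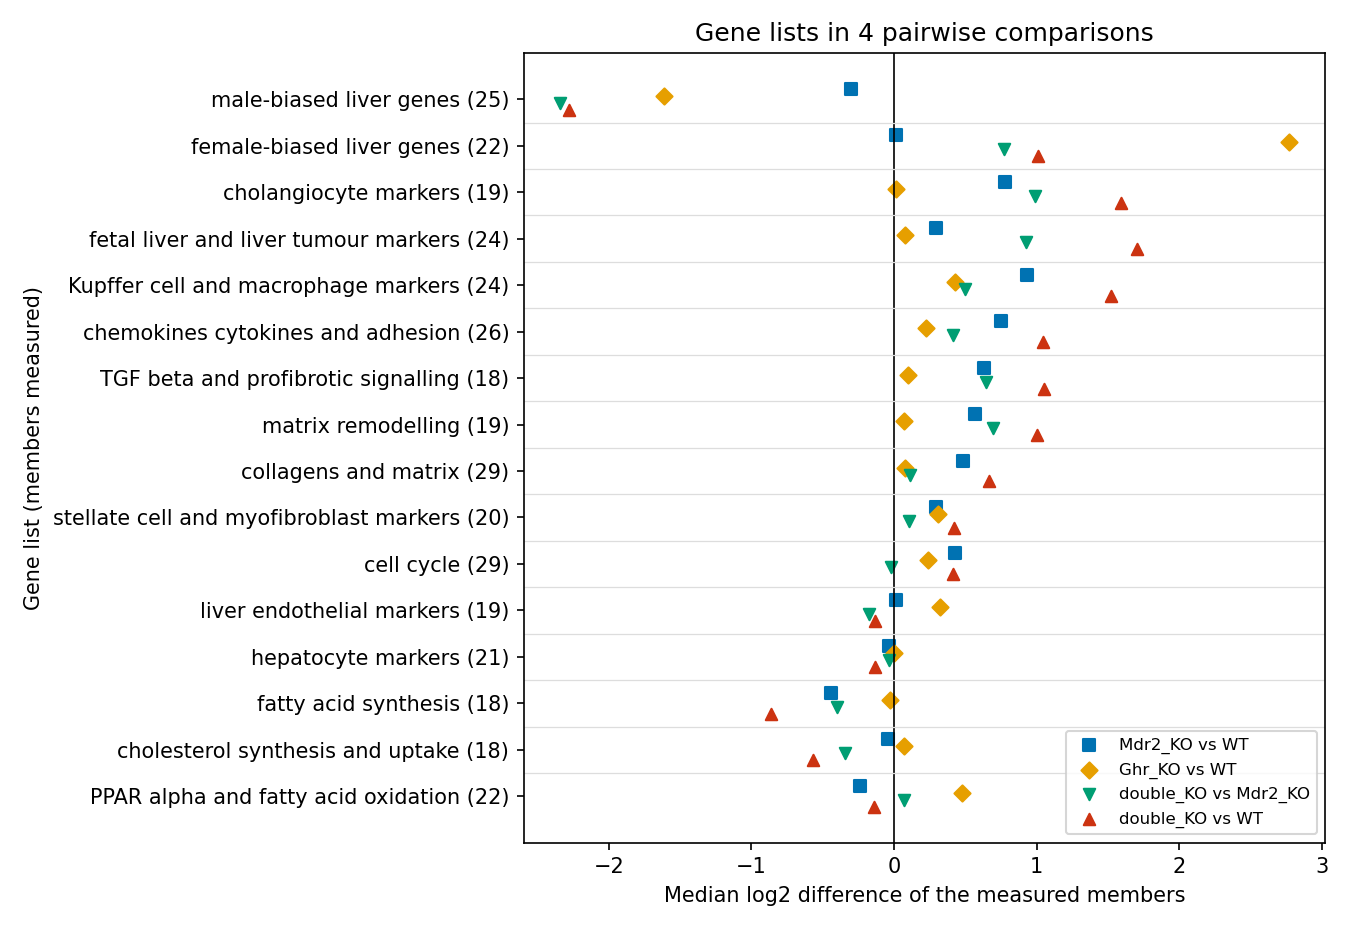
Median log2 difference of 16 gene lists (number of measured members in brackets) in 4 pairwise comparisons, each between 2 single arrays. Cholangiocyte markers stand at 0.78 for MDR2-null against wild type and at 1.59 for double-null against wild type, while collagens and matrix stand at 0.48 and 0.67.

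Loss of both genes against wild type (double-null against wild-type pool) gave larger medians than either single loss in some lists and not in others. The PPAR alpha list had a median of -0.14, against 0.47 in the GHR-null pool. For the female-biased list the median was 1.01, against 2.77 in the GHR-null pool, which carried Xist at 1400. Cholangiocyte markers were at least 1.5-fold higher in 18 of 19 members, with a median of 1.59, fetal liver and tumour markers in 17 of 24, with a median of 1.70, and macrophage markers in 19 of 24, with a median of 1.52. Collagens and matrix genes were higher in 16 of 29, with a median of 0.67. The mucosal glycoprotein Dmbt1 was 34 in the wild-type and 1419 in the double-null pool, Ccl2 was 63 and 1192, and Cd24a was 106 and 1722. The carboxylesterase Ces3b was 51.5-fold and Thrsp 30.5-fold lower, and the fatty acid synthesis list was lower in 11 of 18 members. In all, 722 genes were at least 2-fold higher and 312 at least 2-fold lower among 10487 compared.

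Loss of MDR2 without GHR (double-null against GHR-null pool) gave cholangiocyte markers higher in 17 of 19 members, with a median of 1.71, TGF beta genes in 12 of 18, with a median of 1.09, and collagens in 15 of 29, with a median of 0.59. Dmbt1 was 37 in the GHR-null and 1419 in the double-null pool, and Ccl2 was 63 and 1192. Lower in the double-null pool were Cyp2b13 at 2545 and 28, Cyp4a14 at 24.2-fold and Thrsp at 20.1-fold, and the female-biased list had a median of -0.76. Xist was 1400 in the GHR-null and 17 in the double-null pool. The PPAR alpha list was lower in 10 of 22 members, with a median of -0.50. In all, 495 genes were at least 2-fold higher and 326 at least 2-fold lower among 10514 compared. With arrays centred on hepatocyte markers the counts were 627 and 244. At a 1.5-fold threshold they were 1044 and 1042, and with the level filter at the 75th percentile 224 and 263, so the excess of higher genes was not kept.

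Whether the difference with GHR loss depended on MDR2 was described gene by gene, as the double-null minus MDR2-null difference less the GHR-null minus wild-type difference (log2). Bex1 stood at 3.60, the voltage-gated sodium channel family gene Scn7a at 2.73, Mmp7 at 2.55, Ccn2 at 2.40, Ccl2 at 2.04 and Epcam at 1.81. All of these but Ccn2 were under 100 in both the wild-type and the GHR-null pool, such as Bex1 at 18 and 17. So were some cholangiocyte markers, such as Krt7 at 77 and 71, though not Cdh1. Near background a difference with GHR loss may not show, so such values may largely repeat the double-null against MDR2-null difference. The cholangiocyte list had a median of 0.85 and the fetal liver and tumour list one of 0.51, both above all 10000 random lists. The female-biased list had a median of -1.41, with 14 of 22 members at least 1.5-fold below 0, and the endothelial list one of -0.50, both below all 10000 random lists. Of 38 lists, 10 lay in the highest 2.5% of their random lists and 12 in the lowest 2.5%. Igf1 and Igfals stood at -1.98 and -1.89, Thrsp at -4.03 and Cyp2f2 at -3.47. Xist stood at -6.53 and Cyp2b13 at -6.41, with 1400 and 2545 in the GHR-null pool. Over 10764 genes, 191 were at least 2-fold above and 206 at least 2-fold below 0. With arrays centred on hepatocyte markers the counts were 270 and 141, so the share above 0 was 65.7% in place of 48.1%. The design leaves no residual to test this value.

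Differences that share no array were set against each other across genes, which are not independent replicates. The difference with GHR loss had a Pearson r of 0.462 and a Spearman rho of 0.287 between the pools with and without MDR2, over 10764 genes. At least 2-fold higher in both were 41 genes, where independent lists of these sizes would share 2.55, and 58 were lower in both, against 1.54. Another 4 genes were 2-fold apart in opposite directions. The difference with MDR2 loss had an r of 0.645 and a rho of 0.579, with 185 genes higher in both against 11.7, 42 lower in both against 2.36, and 2 in opposite directions.

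**Figure D3:**
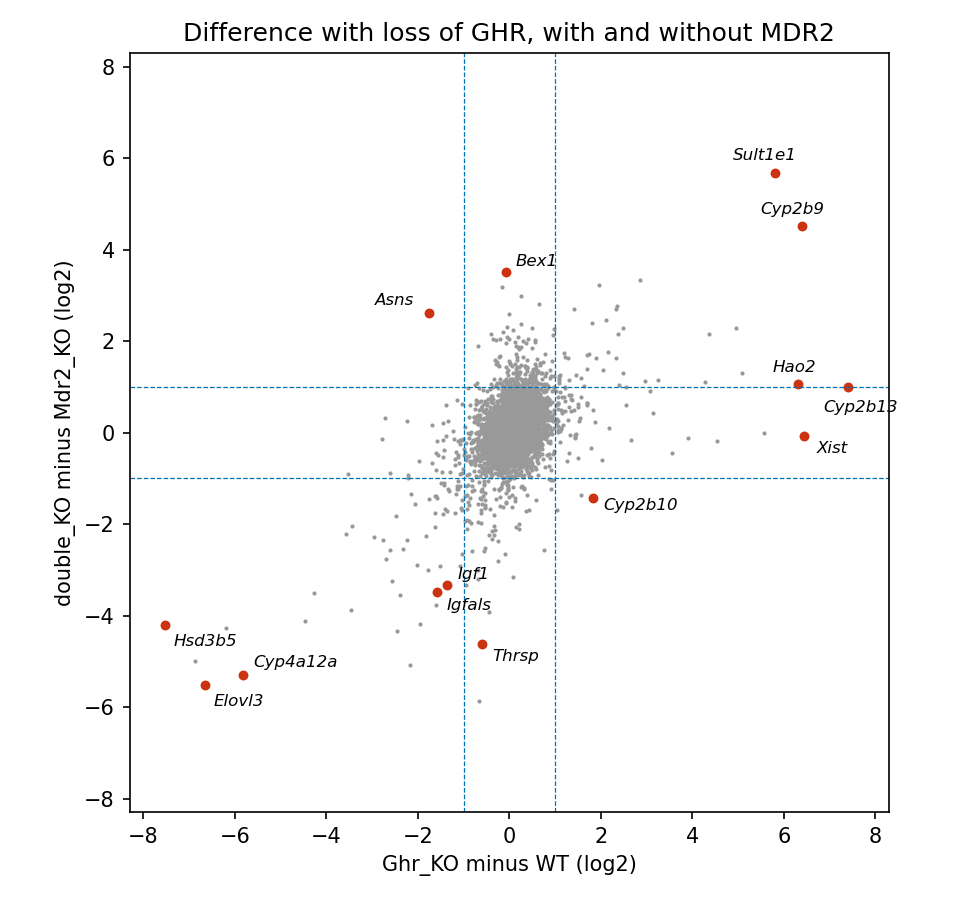
Each point is 1 of 10764 genes, with the log2 difference between the GHR-null and wild-type pools on the x axis and that between the double-null and MDR2-null pools on the y axis. Dashed lines mark 2-fold. Sult1e1 (5.80 and 5.68) is high on both axes, while Xist (6.45 and -0.0825) is high on the x axis alone.

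Averages over both backgrounds were tested with limma, in an additive model of GHR and MDR2 status over the 4 arrays, with 1 residual degree of freedom per gene and Benjamini-Hochberg adjustment over 10764 genes. These p-values weigh each average against the gene's own non-additivity and a prior spread taken from all genes. They measure no spread between pools or mice of a genotype, since no genotype was replicated. With loss of GHR, 22 genes rose and 34 fell. Sult1e1 rose by 5.74 (SE 0.14, adjusted p = 0.000734), Abcd2 by 3.10 (SE 0.17, adjusted p = 0.00622), Scd2 by 2.39 and the cytochrome Cyp2c37 by 2.51 (adjusted p = 0.00765 and 0.00794), each higher in 2 of 2 pairs of arrays. A gene that passes in this model has the same direction in both pairs, so this count and the like counts below add no support. Cyp4a12a fell by 5.56 (SE 0.18, adjusted p = 0.00154), and Slco1a1 fell by 3.66 (adjusted p = 0.00434). Elovl3, Egfr and Saa1, at -6.08, -2.61 and -2.98, fell too (adjusted p = 0.00434, 0.0157 and 0.028), each of the 5 lower in 2 of 2 pairs. Igf1 and Igfals, at -2.34 and -2.53, did not pass (adjusted p = 0.165 and 0.129). Both were non-additive, which inflates the residual they are weighed against. Of 23 male-biased genes tested, 10 fell, and 23 fell when adjusted over the list alone. Of 20 female-biased genes, 5 rose, and 13 rose and 1 fell when adjusted over the list alone. The GHR-null pool, with Xist at 1400, is 1 of the 2 arrays without GHR in these averages. None of the 17 cholangiocyte genes or 26 collagen and matrix genes tested passed for loss of GHR in limma, with 2 and 0 rising when adjusted over the list alone and 4 and 4 at an unadjusted p below 0.05. For cholangiocyte genes this decides little. Their median with loss of GHR was 0.01 with MDR2 present and 0.99 with it absent, and such non-additivity enters the residual of this model.

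With loss of MDR2, 322 genes rose and 82 fell in the same limma model. D17H6S56E-5 rose by 4.36 (SE 0.15, adjusted p = 0.00448), Lcn2 by 3.32 (SE 0.14, adjusted p = 0.00648), Plet1 by 3.34 (SE 0.15, adjusted p = 0.00651) and Mfge8, a secreted phosphatidylserine-binding protein, by 2.82 (SE 0.16, adjusted p = 0.013), each higher in 2 of 2 pairs of arrays. Col1a1 rose by 1.20 (adjusted p = 0.0334), Col3a1 by 0.94 (adjusted p = 0.037), Timp1 by 2.07 (adjusted p = 0.0236), Cd68 by 1.18 (adjusted p = 0.0285) and Ccl2 by 3.22 (adjusted p = 0.0357), each higher in 2 of 2 pairs. Cyp4a31 fell by 2.11 (adjusted p = 0.016), and the antimicrobial peptide gene Leap2 fell by 1.84 (adjusted p = 0.0178), both lower in 2 of 2 pairs. Epcam and Krt19, at 2.14 and 1.11, did not pass (adjusted p = 0.0578 and 0.0507). Among cholangiocyte genes 4 of 17 rose, and 16 when adjusted over the list alone. For collagens and matrix the counts were 6 of 26 and 17, for macrophage markers 9 of 23 and 18 with 1 falling in the second count, and for chemokines 9 of 20 and 15. In the list of fatty acid synthesis 1 of 17 fell, and 12 fell and 1 rose when adjusted over the list alone. Without the level filter, limma called 0 genes for either loss, with 1828 and 2927 genes at an unadjusted p below 0.05. With arrays centred on hepatocyte markers it called 14 and 22 genes for GHR and 99 and 21 for MDR2.

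**Figure D4:**
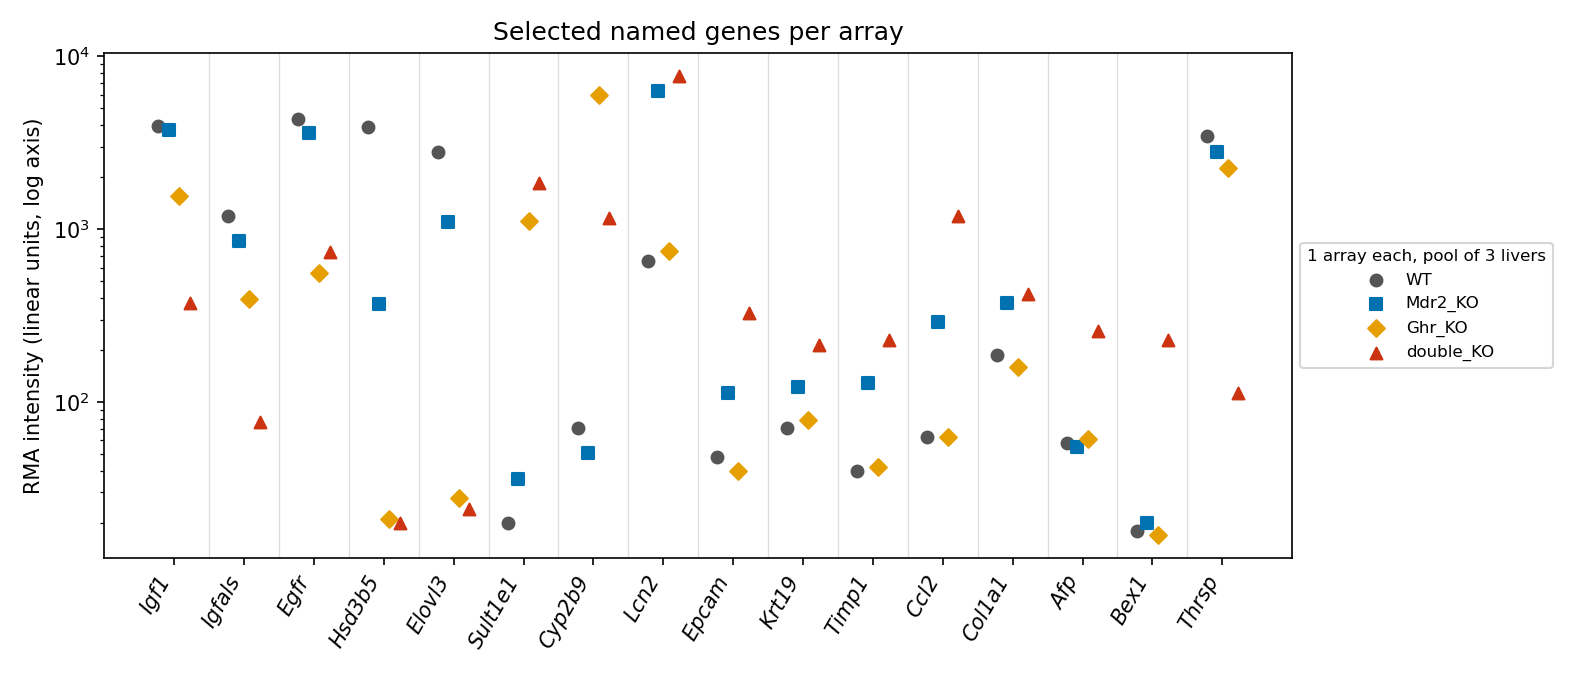
Intensity of 16 named genes on a log axis, with 1 point per array (a pool of 3 livers per genotype). Igf1 stands at 3951, 3766, 1546 and 374 and Ccl2 at 63, 290, 63 and 1192 in the wild-type, MDR2-null, GHR-null and double-null pools.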

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

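Of the tests in this part, only that on X-linked genes escaping inactivation was chosen before its result was seen; the others were chosen after. A few named genes moved at least 2-fold in opposite directions in the 2 backgrounds, and these differences were not tested, since each rests on 4 single arrays. Asns was 1.75 lower on the log2 scale with loss of GHR when MDR2 was present (a difference of -1.75) and 2.61 higher when it was absent, a difference of 4.36. Cyp2b10 was higher by 1.83 with MDR2 present and stood at -1.42 with it absent, a difference of -3.25. With loss of MDR2, Cxcl9 was higher by 1.12 when GHR was present and stood at -2.20 when it was absent, a difference of -3.32. Susd4, a male-biased gene, stood at -1.17 and 1.46, a difference of 2.63. Each of these differences uses the GHR-null pool, which carried Xist at 1400. Cyp2b10 was 1677 in that pool, against 472, 364 and 136 in the wild-type, MDR2-null and double-null pools. Among rows with several or no gene symbols, which no comparison used, 59 were at least 2-fold above the wild-type pool in the MDR2-null pool (96 below, of 4553), 114 in the GHR-null pool (99 below, of 4619) and 263 in the double-null pool (126 below, of 4712).

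Xist was 1400 in the GHR-null pool and at most 18 in the others. Loss of GHR by itself as the cause is argued against by the double-null pool, where Xist differed from the MDR2-null pool by -0.0825 (log2). A share of female RNA in the pool stays open: 4 X-linked genes that escape inactivation had a median of 0.19 above the mean of the other arrays (range 0.01 to 0.28), short of the 0.23 set beforehand, and 3 Y-linked genes a median of -0.22. The 0.23 is the spread of a pairwise difference of single genes. Female RNA in only part of a pool would shift escape genes only in part, so falling short of 0.23 decides nothing. Female RNA as the whole cause of the lower male-biased genes is argued against, since their median lay 1.38 below that of the Y-linked genes (a difference of -1.38, bootstrap interval over genes -2.65 to -1.11), while a share of female RNA dilutes both alike. How much of the higher female-biased genes it could account for is not settled, since Cyp2b13 was 2545 in the GHR-null and 28 in the double-null pool while Sult1e1 was 1114 and 1845.

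H2-Ea, which encodes a chain of a class II histocompatibility molecule that some mouse strains do not express, was 299 and 822 in the pools with MDR2 and 2927 and 2854 in those without, and it drew attention as 1 of the highest genes in the MDR2-null pool. More antigen-presenting cells stay open: in the double-null against the GHR-null pool, arrays not used to pick it, H2-Ea exceeded the median of 5 other class II genes by 0.50, while the farthest of these lay 0.37 from that median, and this rests on 1 gene. Another H2 haplotype in the pools without MDR2, that is, a difference of strain background, may contribute and cannot be told apart from loss of MDR2, since haplotype and genotype could go together in all 4 pools. D17H6S56E-5, which lies 34 measured genes from H2-Ea on the same chromosome and had the highest ratio of the MDR2-null to the wild-type pool, was 45 and 79 with MDR2 and 1016 and 1480 without. Of the 25 genes nearest to H2-Ea that passed the level filter (20 measured genes to each side, class II genes left out), 0 were 2-fold apart the same way in both MDR2 comparisons, against 2.11% of all genes, and so few genes decide nothing.

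Cholangiocyte, macrophage and matrix genes were higher in the double-null than in the wild-type pool. For cholangiocyte markers, a smaller share of hepatocytes that raises markers of every other cell type alike is argued against: their median exceeded the endothelial median by 1.73 (bootstrap interval over genes 1.41 to 2.47). No such interval was computed for macrophage markers or for collagens and matrix, with medians of 1.52 and 0.67 against -0.14 for endothelial markers. The value of 1.73 does not address a share made smaller by more bile duct cells or macrophages. On the scaling between arrays, the cholangiocyte median was 1.66 with arrays centred on hepatocyte markers. That centring moves every gene of a comparison by 1 constant, here 0.07, so the median was bound to stay near 1.59 and this decides little. A constant shift between the arrays would also raise hepatocyte markers, whose median was -0.13. Macrophage and matrix genes were not checked in this way. Whether these pools held more bile duct cells and macrophages or more of these transcripts per cell stays open, and the design names loss of both genes as the biological difference; limma tested each loss on average over both backgrounds, and the joint loss against wild type was not tested.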

How the results depend on the processing

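Leaving out the sex-biased and sex-linked lists was chosen after the data were seen; the other alternatives were fixed before the data were examined. The cause of the shifts was not tested, except that a lower fold threshold counts more genes and a higher level filter counts fewer. At a 1.5-fold threshold the higher and lower counts were 622 and 366 for MDR2-null against wild type, 426 and 248 for GHR-null against wild type, 754 and 408 for double-null against MDR2-null, 1436 and 794 for double-null against wild type, 1044 and 1042 for double-null against GHR-null, and 568 and 723 for non-additivity. With the level filter at the 75th percentile the higher and lower counts were 106 and 54 for MDR2-null against wild type, 115 and 128 for double-null against MDR2-null, 339 and 241 for double-null against wild type, 224 and 263 for double-null against GHR-null, and 89 and 164 for non-additivity, so that lower genes outnumbered higher ones in both double-null comparisons with a single-null pool, unlike at the median filter. In limma that filter left 11 rising and 21 falling genes for loss of GHR and 57 and 12 for loss of MDR2. No level filter left 0 and 0 for each loss, with 19938 genes tested and a prior of 1.41 degrees of freedom in place of 4.34. Hepatocyte centring left 14 and 22 for loss of GHR and 99 and 21 for loss of MDR2. Without the sex-related lists, 22 genes fell with loss of GHR and 134 with loss of MDR2. All other counts were within 1.5 times, and the 2 correlations across backgrounds (Pearson r) ranged from 0.400 to 0.526 for GHR and 0.594 to 0.667 for MDR2. Of 228 list medians, all kept within 0.23 of their value under the 4 settings of scaling and row choice, though some near 0 changed sign. With members passing the level filter, 30 moved further and that of lymphocyte and plasma cell markers in double-null against MDR2-null turned from -0.19 to 0.27, with fewer members in the median. Of 1064 differences of named genes, 14 moved by more than 0.23 with the mean of all rows and none did under the scalings. Median and hepatocyte centring shift all genes of a comparison by 1 constant, at most 0.13 in size in the pairwise comparisons. No list median or gene could therefore move by 0.23 under them, and only cyclic loess and the mean of all rows could show such a move. No paired analysis was possible because each genotype has 1 array. Leaving out an array leaves no residual or no comparison. Low intensities limit lists such as neutrophil markers, lymphocyte markers and cell cycle genes, of which limma tested 1 of 13, 4 of 20 and 14 of 29 measured members.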

Other observations

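Lists that the comparisons above did not describe are given here with no test chosen. Neutrophil markers had medians of 0.21 in the MDR2-null and 0.14 in the GHR-null pool against wild type, and -0.13 in the double-null against the MDR2-null pool, with at most 1 of 13 members at least 1.5-fold higher. Lymphocyte and plasma cell markers had medians of 0.23 and 0.27 in the MDR2-null and GHR-null pools against wild type, with 3 and 6 of 20 members higher. Pericentral hepatocyte genes had a median of 0.14 in the MDR2-null and 0.36 in the GHR-null pool, and in the double-null against the MDR2-null pool the glutamine synthetase Glul was 2.36-fold lower. Periportal genes had medians of -0.29 and 0.06 in these pools against wild type, the second turning below 0 with median and hepatocyte centring, and -0.46 in the double-null pool. Glucose handling genes had medians of -0.01 and 0.11, both changing sign with median centring and the first with cyclic loess, and the glucose-6-phosphatase gene G6pc was 3.19-fold lower in the double-null than in the MDR2-null pool. The circadian clock list had medians of 0.01, which turned below 0 with hepatocyte centring, and 0.15, with Ciart 2.74-fold lower in the GHR-null pool.

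Erythroid markers, a sign of blood in the sample, had medians of 0.18 and 0.01 in the MDR2-null and GHR-null pools against wild type, the second turning below 0 with every scaling tried. In the list of pancreas, fat, gut and muscle markers the medians were -0.10 and -0.41, with Acta1 at -1.11 in the GHR-null pool. Genes near Abcb4 on its chromosome had a median of 0.34 in the MDR2-null and 0.56 in the double-null pool against wild type (percentiles 99.97 and 99.99 of the random lists), and of 0.22 in the double-null against the MDR2-null pool, which both lack MDR2 (percentile 99.28, 3 of 12 members higher), with the multidrug transporter Abcb1b 2.19-fold higher in the MDR2-null pool. Genes near Ghr had medians of 0.00 in the GHR-null pool and 0.12 in the double-null against the MDR2-null pool, with the complement gene C6, also on the male-biased list, 6.75-fold and 5.06-fold lower. Segments of the strain in which a gene was targeted stay linked to it in knockout mice, and these values do not separate that from an effect of the loss.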
